A study of Mus musculus with 10 samples.

How the data were processed

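The series holds RNA sequencing of popliteal lymph nodes taken on day 15 from male BALB/c mice of 6 to 8 weeks. The 10 libraries fall into 3 groups by their treatment label. Control received saline in the hind paw (3 libraries, numbered 15, 16 and 17). AIA received 0.1 ml of complete Freund's adjuvant, an oil emulsion with killed mycobacteria used to induce arthritis (4 libraries, 5, 10, 31 and 38). Acu received the adjuvant and acupuncture, which the series title places at ST36, a point below the knee (3 libraries, 4, 6 and 28). The labels' protocols also mention a sham acupuncture group, which was not analysed here. The groups share no replicate number, so no library of 1 group was paired with a library of another. The labels do not say that each library came from its own mouse, so p-values measure the spread between these libraries.

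Total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.16.1 and the genome build mm10 are named, without role or order, per the submitters' processing notes. Whether reads were counted by strand is not given in the sources used here, so genes that overlap, antisense pairs and near-identical paralogs are uncertain. The authors deposited FPKM (fragments per kilobase of gene and 1e+06 reads) for 54987 genes in each library, with gene lengths, names and coordinates. In each library the product of FPKM and gene length was a whole multiple of a single step for 100% of genes above 0, within a tolerance of 0.01 of a step, which gave back the reads behind each value. These recovered reads ranged from 13269763 to 18926894 per library. The library size that the step implies was in a constant ratio to the median-of-ratios size factor of the recovered reads, so the deposited FPKM had already been scaled between libraries in that way.

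FPKM were scaled between libraries by the median of ratios to the geometric mean, which moved them very little, and log2(FPKM + 1) was used for tests. The pseudocount of 1 makes fold changes of low genes smaller than the true ones. Genes with an FPKM of at least 0.5 in at least 3 libraries were tested (17010 genes). limma 3.58.1 in R 4.3.3 fitted all 10 libraries together, with a mean-variance trend in the empirical Bayes step. Each of the 3 comparisons was adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. In the text SE is limma's moderated standard error of the log2 fold change, and SD is the spread between libraries in FPKM.

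A total of 36 gene lists (cell types, cell states, pathways and tissues that lie next to a lymph node) were fixed before the data were examined, together with the tests, the filter, the thresholds and most of the other settings tried. The 35 lists with at least 5 tested members were tested by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 105 list and comparison pairs. Camera was repeated with an estimated correlation, and fry was run as a test of whether the genes of a list moved 1 way on balance. The number of list members past the threshold is given over all genes tested and adjusted over the list alone. Genes named in the text follow a rule that was also fixed beforehand. It takes, in each comparison, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with a mean FPKM of at least 1 in the higher group and no overlap between libraries. Where fewer than 4 genes passed it takes the 8 genes with the smallest p. It adds up to 3 members of each list described, a set of genes for immune subsets, macrophage states and noradrenaline signalling, and the immunoglobulin constant genes. Immunoglobulin segments, predicted genes and unnamed genes were left out of the ranking. The results of some genes that the rule names are not reported here.

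The share of summed FPKM taken by 429 immunoglobulin genes was compared between groups by a two-sided exact permutation test of the difference in means, adjusted over the 3 comparisons. The correlation across genes of the fold changes AIA minus Control and Acu minus AIA was set beside 100 simulated unchanged groups that share the AIA libraries, and beside splits of the AIA libraries 2 and 2. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading, exact tests and figures.

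The fit was tested on simulated reads with known changes drawn for the real genes and library sizes. With a dispersion of 0.1 it recovered 8.96%, 85.1% and 98.5% of the genes changed 2-, 4- and 8-fold between AIA and Control, and called 14 of 17527 unchanged genes. The same shares were 7.46%, 80.6% and 98.5% for Acu against AIA, and 11.9%, 74.6% and 93.9% for Acu against Control. With each gene's dispersion taken from the real libraries the shares fell to 1.49%, 14.9% and 42.4% for AIA against Control, to 0%, 8.96% and 22.7% for Acu against AIA, and to 0%, 13.4% and 28.8% for Acu against Control. The number of genes fitted was between 17469 and 17766. No pair of libraries was the same within counting noise: the closest pair of the same group, AIA 5 and AIA 31, differed beyond noise in 54.2% of genes.

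Other settings changed the pseudocount, the filter, the scaling, the libraries in the fit, the empirical Bayes step, the library weights and the threshold, and left out each library in turn. Other alternatives were added after the data were seen. They left out the libraries labelled Control 17 and Acu 4, left out Control 15 as well, left out AIA 10 as well, and ran limma's voom on the recovered reads. Tests of those fits used the genes that passed the same filter in the libraries kept (16067, 15653 and 15448 genes). The filter still asked for at least 3 libraries. Genes above it only in Acu or only in Control thus could not be tested in those fits, while genes above it only in AIA could. A fit that keeps 1 Control library assumes that it varies like the libraries of the other groups.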

Results

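RNA was measured in popliteal lymph nodes, which drain the hind paw, 15 days after injection. Control (n = 3) received saline and AIA (n = 4) received complete Freund's adjuvant, which drives arthritis. Acu (n = 3) received the adjuvant and acupuncture at ST36. The series title asks how acupuncture acts on the growth and polarization of immune cells and on sympathetic activity. The recovered reads ran from 13269763 in AIA 10 to 18926894 in Control 15. Control 16 had 14609416 and the library labelled Control 17 had 18731698. AIA 5, 31 and 38 had 14395861, 16148825 and 16819387. The library labelled Acu 4 had 18330702, Acu 6 had 16391068 and Acu 28 had 16357118. Genes above 0 numbered 15116 in AIA 10 and between 21224 and 24411 in the other libraries.

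Prl8a2, a decidual prolactin of the pregnant uterus, reached 10782 FPKM in the library labelled Control 17 and 3916 FPKM in the library labelled Acu 4. It was at most 1.37 FPKM in the other 8 libraries. All 13 decidual and uterine genes examined were above 1 FPKM in both libraries, at a mean log2(FPKM + 1) of 9.32 and 8.46. In the other 8 libraries that mean lay between 0.374 and 0.821, and 6 of the 13 genes were above 1 FPKM in at least 1 library. Trophoblast genes, which mark the placenta, stood at 8.80 in the library labelled Acu 4, with 11 of 11 above 1 FPKM. They stood at 2.59 in the library labelled Control 17, with 7 of 11. Embryonic globins were above 1 FPKM in that library alone, 3 of 3. Xist, which is made from the inactive X chromosome of females, was 87.5 and 60.3 FPKM in these libraries and at most 0.129 elsewhere. The 4 Y-linked genes averaged 0.0217 and 0 on the log2 scale there, against 2.65 to 3.10 in the other 8 libraries. The labels give every animal as male.

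B cell genes such as Cd79a averaged 6.00 in Control 16 and 5.70 to 6.41 in the AIA libraries. They averaged 0.83 in Control 15, 0.384 in the library labelled Control 17 and 0.445 in the library labelled Acu 4. T cell genes followed, with 4.52 in Control 16, 4.91 to 5.16 in AIA, and 0.748, 1.09 and 0.985 in those 3 libraries. Adipocyte genes averaged 10.1 in Control 15 and 8.03 in Control 16, against 1.72 to 4.02 in the AIA libraries. Skeletal muscle genes averaged 6.92 in Control 15 and 8.79 in Control 16, against 1.04 to 6.10 in the AIA libraries. Control 16 was the only Control library with lymphocyte genes near the AIA level, and it held fat and muscle genes as well. The library labelled Control 17 and the library labelled Acu 4 correlated with each other at 0.928 across genes. With the other libraries of their own groups they correlated at 0.637 to 0.721 and at 0.644 to 0.652. AIA 31 and Acu 28 had the highest value of any pair, 0.969.

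**Figure D1:**
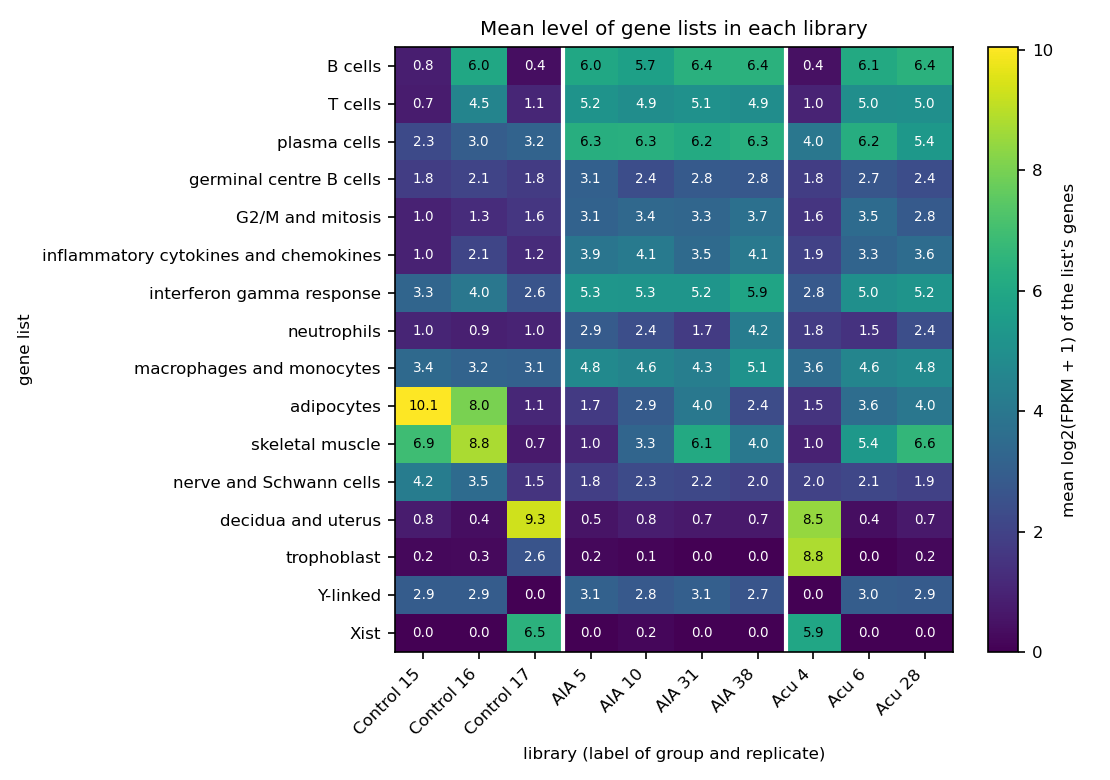
Mean log2(FPKM + 1) of gene lists (vertical axis) in each of the 10 libraries (horizontal axis), as colour. Decidual genes stood at 9.32 and 8.46 in the libraries labelled Control 17 and Acu 4, and B cell genes at 0.83 in Control 15 against 6.00 in Control 16.

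AIA was compared with Control to ask what the adjuvant changed in the draining node. Jchain, which joins the units of secreted IgM and IgA in plasma cells, rose from 3.54 ± 2.43 FPKM in Control (SD, n = 3) to 1936 ± 479 FPKM in AIA (SD, n = 4). Its log2 fold change was 8.90 (SE 0.93, limma adjusted p = 0.0297). The gene lies on chromosome 5 of mm10 at 88519809 to 88527891, minus strand. Bhlha15, a transcription factor of secretory cells, rose by 3.24 (SE 0.40, limma adjusted p = 0.0494), from 0.343 ± 0.442 to 11.4 ± 1.66 FPKM. Olfm2, a secreted olfactomedin of vessels and nerves on chromosome 9 at 20667690 to 20746349, fell by 2.41 (SE 0.28, limma adjusted p = 0.0332), from 4.98 ± 2.39 to 0.0664 ± 0.0801 FPKM. An unnamed transcript of 532 bases on chromosome 1 at 162873100 to 162873946 fell by 1.89 (SE 0.20, limma adjusted p = 0.0297). It went from 2.92 ± 0.442 to 0.0555 ± 0.111 FPKM, and was chosen after its values were seen. All 4 genes had no overlap between the groups.

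These 4 genes, 2 higher and 2 lower, were all that limma called among 17010. At an unadjusted p under 0.05 there were 4246, and 1148 had an adjusted p under 0.1. Groups did not overlap in 25.3% of genes, against 5.71% by chance. limma's voom called 0 and array weights called 3319. The count was 1708 without the library labelled Acu 4, 956 without the library labelled Control 17, 8 without AIA 10 and 2 without Acu 6. It was 0 without any 1 of Control 15, Control 16, AIA 5, AIA 31, AIA 38 and Acu 28. Slpi, an inhibitor of neutrophil proteases, stood 7.57 higher in AIA (SE 1.12) and Ccl2, which draws monocytes, 3.34 higher (SE 0.49), both with a limma adjusted p of 0.0545. Gpihbp1, Vegfa and Arap3, genes of blood vessels and their growth, stood at −4.57, −3.27 and −2.55 with the same adjusted p. The Control libraries held decidual, fat or muscle genes. These falls, and those of Olfm2 and the unnamed transcript, thus cannot be assigned to the adjuvant. Il1b stood 3.90 higher (SE 0.67, adjusted p = 0.0552) and Mki67, a protein of dividing cells, 3.47 higher (SE 0.71, adjusted p = 0.0638).

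Genes of dividing cells and of plasma cells stood higher in AIA over all 10 libraries. Apart from Jchain in the plasma cell list, no list member passed over all genes tested. The G2/M and mitosis list had a median log2 fold change of 2.07, with 22 of 24 genes past the threshold adjusted over the list alone. Plasma cell genes had a median of 2.87, with 13 of 16 adjusted over the list alone. Adjusted over the list alone, 18 of 25 S phase genes, 20 of 23 interferon gamma response genes, 16 of 22 cytokine and chemokine genes and 12 of 17 M1-type macrophage genes were higher. The M2-type list had 3 higher and 3 lower of 16, and its camera adjusted p was 0.768. Among the other immune lists the counts higher were 10 of 19 for macrophages and monocytes, 6 of 19 for neutrophils, 7 of 10 for naive T cells and 4 of 14 for Th1 and cytotoxic cells. They were 3 of 12 for regulatory T cells and 1 of 8 for Th17, and germinal centre genes had 7 higher and 1 lower of 14. T cell, B cell, Th2, follicular helper, dendritic, NK and mast cell lists had 0. Yet all 16 T cell and all 16 B cell genes stood higher, with medians of 3.185 and 3.71. Camera's adjusted p was 1.07e-06 and 5.25e-06 for these lists, and 0.421 for both with an estimated correlation. The Control libraries were far apart, at 0.748 to 4.52 for T cells and 0.384 to 6.00 for B cells. Type I interferon genes had 10 of 25 higher, ribosomal proteins 14 of 26, the unfolded protein response 4 of 20, and complement 4 higher and 1 lower of 16. Lower genes were 9 of 18 for endothelium, 5 of 7 for erythroid cells, 3 of 15 for the glucocorticoid response, 2 of 13 for adrenergic genes and 2 of 16 for adipocytes. All 16 adipocyte genes stood lower in AIA, with a median of −3.84, and the Control libraries ran from 1.12 to 10.1. Nerve genes had 2 higher and 3 lower of 8. The muscle, fibroblastic, immediate-early and mitochondrial lists had 0. Camera with the preset correlation called 24 of the 35 lists. Fry called 2, plasma cells (adjusted p = 0.0190) and cytokines (adjusted p = 0.0200). Camera with an estimated correlation called 0. The smallest adjusted p with an estimated correlation was 0.382. Keratinocyte genes had 3 measured members and were not tested, with means of 1.58 ± 1.60 in Control and 0.182 ± 0.108 in AIA.

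Without the libraries labelled Control 17 and Acu 4, a choice made after the data were seen, limma called 2166 of 16067 genes between AIA (n = 4) and Control (n = 2). Of these 688 rose and 1478 fell, and Jchain and Bhlha15 were among them. Olfm2 and the unnamed transcript were below the filter in this fit. Without Control 15 as well, 486 genes were called (75 higher, 411 lower), 450 of them among the 2166. Adjusted p-values in the following paragraphs on these groups are limma's from the fit without these 2 libraries, and the values without Control 15 are given for genes that then did not pass. Counts of list genes are over all genes tested, with the count adjusted over the list alone in brackets.

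Immunoglobulin and secretory genes rose most. Ighg1, the heavy chain of IgG1, rose by 11.70 (SE 0.70, adjusted p = 6.83e-04), to 8152 ± 5023 FPKM in AIA (SD, n = 4) from 0.542 in Control 15 and 1.83 in Control 16. Ighg2b rose by 9.12, Ighg3 by 9.63, Ighg2c by 9.05, Igha by 5.07, Ighm by 4.32 and the light chain Igkc by 8.12. Ighd (3.86, adjusted p = 0.167) and Ighe (2.90, adjusted p = 0.0528) did not pass. Ighg2c is uncertain because BALB/c mice carry another allele of it than the reference, and the segments of this locus share reads. Jchain rose by 8.31 (SE 0.53, adjusted p = 6.83e-04) and Mzb1, a chaperone for antibody assembly, by 6.86 (adjusted p = 0.00924). Control 15 held few B cell genes, and part of these rises rested on it. Leaving it out gave log2 fold changes of 4.33 for Mzb1, 5.54 for Igkc and 2.14 for Ighm. Those of Jchain and Ighg1 were 8.18 and 11.24. Eaf2, a partner of RNA polymerase elongation found in plasma cells, rose by 4.10 and Manf, an endoplasmic reticulum stress protein, by 2.70. Plasma cell genes past the threshold were 12 (15) of 16, all higher, and 8 (14) without Control 15. For the unfolded protein response they were 9 (12) of 20. Gcsam, a signalling protein of germinal centre B cells, rose by 1.79. The germinal centre list had 4 (5) higher and 1 (1) lower of 14, and the follicular helper list 1 (4) of 9. Without Control 15 the count was 1 (12) for the unfolded protein response, 0 (3) higher and 0 (1) lower for germinal centre genes and 0 (0) for follicular helper genes. The adjusted p was then 0.0885 for Ighg2c, 0.232 for Ighm, 0.190 for Igkc and 0.127 for Gcsam.

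Mki67 rose by 3.53 (SE 0.44, adjusted p = 0.00334), to 52.5 ± 12.1 FPKM in AIA from 1.86 and 5.99 FPKM in Control 15 and 16. Ccnb2, a mitotic cyclin, rose by 2.84, Top2a by 2.86, and the S phase genes Uhrf1, Mcm3 and Rrm2 by 2.39, 2.32 and 3.11. Of the lists, 21 (22) of 24 G2/M genes and 16 (22) of 25 S phase genes were higher. Without Control 15 these counts were 6 (20) and 0 (7). Uhrf1, Mcm3 and Rrm2 then had adjusted p-values of 0.0598, 0.0632 and 0.0587.

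Slpi rose by 9.05 (SE 0.56, adjusted p = 6.83e-04), and S100a9 and S100a8, which together form calprotectin in neutrophils, rose by 6.21 (SE 0.87) and 5.53 (SE 1.06). S100a9 reached 215 ± 131 FPKM in AIA and was 2.46 and 0.498 FPKM in Control 15 and 16. Il1b, Ccl2 and Ccl3 rose by 3.87, 3.64 and 2.19, and Clec7a, the receptor for fungal glucans, by 3.80. Il10, a cytokine that restrains inflammation, rose by 1.73 (adjusted p = 0.0258). Il1f9, Vcam1, Ly6c2, Cd5l, Itgax and the acute phase gene Saa3 rose by 2.23, 2.38, 3.69, 3.38, 1.66 and 4.53. Serpina3g and Ccl8 rose by 4.62 and 4.60. Genes higher were 7 (8) of 19 for neutrophils, 8 (11) of 19 for macrophages and monocytes and 10 (16) of 22 for cytokines. Without Control 15 those counts were 1 (4), 3 (12) and 4 (10). The adjusted p was then between 0.0548 (Serpina3g) and 0.207 (Il10) for S100a8, Serpina3g, Ccl8, Saa3, Il10, Ly6c2, Cd5l and Il1f9.

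Genes tied to M1-type macrophages, which are driven by interferon gamma, rose in 9 (13) of 17 cases. M2-type genes, which follow interleukin 4, went both ways, with 3 (3) higher and 5 (8) lower of 16. Retnla, a secreted protein of M2-type macrophages, fell by 5.21 (SE 0.48, adjusted p = 0.00273), from 84.1 and 54.3 FPKM in Control 15 and 16 to 1.01 ± 0.985 FPKM in AIA. Mgl2, a lectin of the same cells, fell by 2.92, while Clec7a, also on the M2-type list, rose by 3.80. Control 15 and Control 16 also held fat genes, so the falls cannot be assigned to macrophages of the node. The enzymes Nos2 (−0.05) and Arg1 (1.00) and the receptor Mrc1 (−1.05), used to tell these states apart, did not pass, and neither did Tnf (1.59). Isg20, Iigp1 and Cxcl9, which interferons induce, rose by 2.52, 2.30 and 2.40, with 13 (19) of 22 interferon gamma genes and 9 (15) of 25 type I interferon genes higher. Without Control 15 the counts were 3 (8) for M1-type, 2 (2) higher and 4 (4) lower for M2-type, 0 (10) for interferon gamma and 0 (2) for type I interferon genes. Isg20, Iigp1 and Cxcl9 then had adjusted p-values of 0.0703, 0.0587 and 0.0558.

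Among T cell genes Gzmb and Prf1, which kill target cells, rose by 2.95 (SE 0.46) and 1.86, and Batf by 3.01. Over all 10 libraries Prf1 stood the other way, at −0.67 (adjusted p = 0.832). Ebi3 rose by 1.64. Tbx21 (1.21), Ifng (0.96), Foxp3 (1.36) and Cd3e (2.49) did not pass. Without Control 15 the value was 0.49 for Cd3e, 1.53 for Batf, 2.74 for Gzmb, 1.52 for Prf1 and 1.23 for Ebi3. Gzmb, Prf1, Batf and Ebi3 then had adjusted p-values of 0.0684, 0.178, 0.110 and 0.205. The Th1 and cytotoxic list had 6 (9) of 14 higher and NK cells 4 (6) of 10. Regulatory T cells had 4 (6) of 12 higher and 0 (1) lower, dendritic cells 2 (1) of 17 higher and naive T cells 1 (6) of 10. The Th17 list had 1 (1) higher and 1 (2) lower of 8. T cells had 0 (12) of 16, and the B cell and Th2 lists 0 (0). Without Control 15 the count was 0 (2) for the Th1 and cytotoxic list and 1 (1) for dendritic cells, and Th17 had 0 (1) higher and 1 (1) lower. T cells, naive T cells, regulatory T cells and NK cells then had 0 (0). Il17a, Il6 and Th were too low to test, and Il17a was listed at 0 in all 3 Control libraries and at 0.546 ± 0.741 FPKM in AIA.

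Fat genes fell most. The adipocyte list averaged 10.1 in Control 15 and 8.03 in Control 16, against 1.72 to 4.02 in the AIA libraries. Skeletal muscle genes averaged 6.92 and 8.79, against 1.04 to 6.10. Tissue content thus differed along with the group. The falls in this paragraph, that of Adrb3 included, cannot be told apart from such a difference and are not assigned to the adjuvant. Adipoq, the fat hormone adiponectin, fell by 7.30 (SE 0.81, adjusted p = 0.00291), from 1299 and 338 FPKM in Control 15 and 16 to 4.80 ± 5.92 FPKM in AIA. Car3, Thrsp, Cyp2e1, Gpd1, Cfd, Pck1, Ces1d, Plin1 and Cidea fell by 6.42 to 7.89. All 16 (16) adipocyte genes were lower, and 11 (16) without Control 15. Adrb3, the adrenergic receptor of fat cells, fell by 6.12 (SE 0.57, adjusted p = 0.00273), from 213 and 71.3 FPKM to 0.974 ± 1.08 FPKM. Maob, which breaks down amines, fell by 2.73. These were the 2 (4) lower of 10 adrenergic genes. Nerve and Schwann cell genes had 1 (2) higher and 3 (5) lower of 7. Muscle genes had 5 (17) of 17 lower, such as Myh2 (−3.28) and Ttn (−2.60). Endothelium had 1 (2) higher and 7 (8) lower of 18, such as Tek (−2.65). The erythroid list had 4 (5) of 6 lower, such as Hbb-bt (−3.18), and 0 (1) higher. The glucocorticoid response had 5 (8) of 15 lower, such as Sult1a1 (−3.06) and Dusp1 (−2.14), and mast cells 2 (3) of 9. Fibroblastic genes had 1 (2) higher, Bst1 (2.35), and 1 (5) lower, Lum (−2.71), of 18. Mitochondrial genes had 2 (5) of 13 lower. Ribosomal proteins had 3 (16) of 26 higher, such as Rpl5 (1.89), complement 1 (4) of 14, and immediate-early genes 0 (0) of 15. Without Control 15 the counts lower were 0 (15) for muscle, 2 (5) for endothelium, 2 (2) of 5 for erythroid cells, 1 (2) of 9 for adrenergic genes, 3 (3) for nerve, 0 (2) for mast cells and 1 (1) for fibroblastic genes. The glucocorticoid, mitochondrial and ribosomal protein lists then had 0 (0), and nerve and endothelium 0 (0) higher. Without Control 15 the adjusted p was between 0.0515 (Pck1) and 0.244 (Rpl5) for Car3, Cfd, Pck1, Maob, Sult1a1, Dusp1, Bst1, Myh2, Ttn and Rpl5. Over the 35 lists camera called 27 with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.344. Fry called 22.

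**Figure D2:**
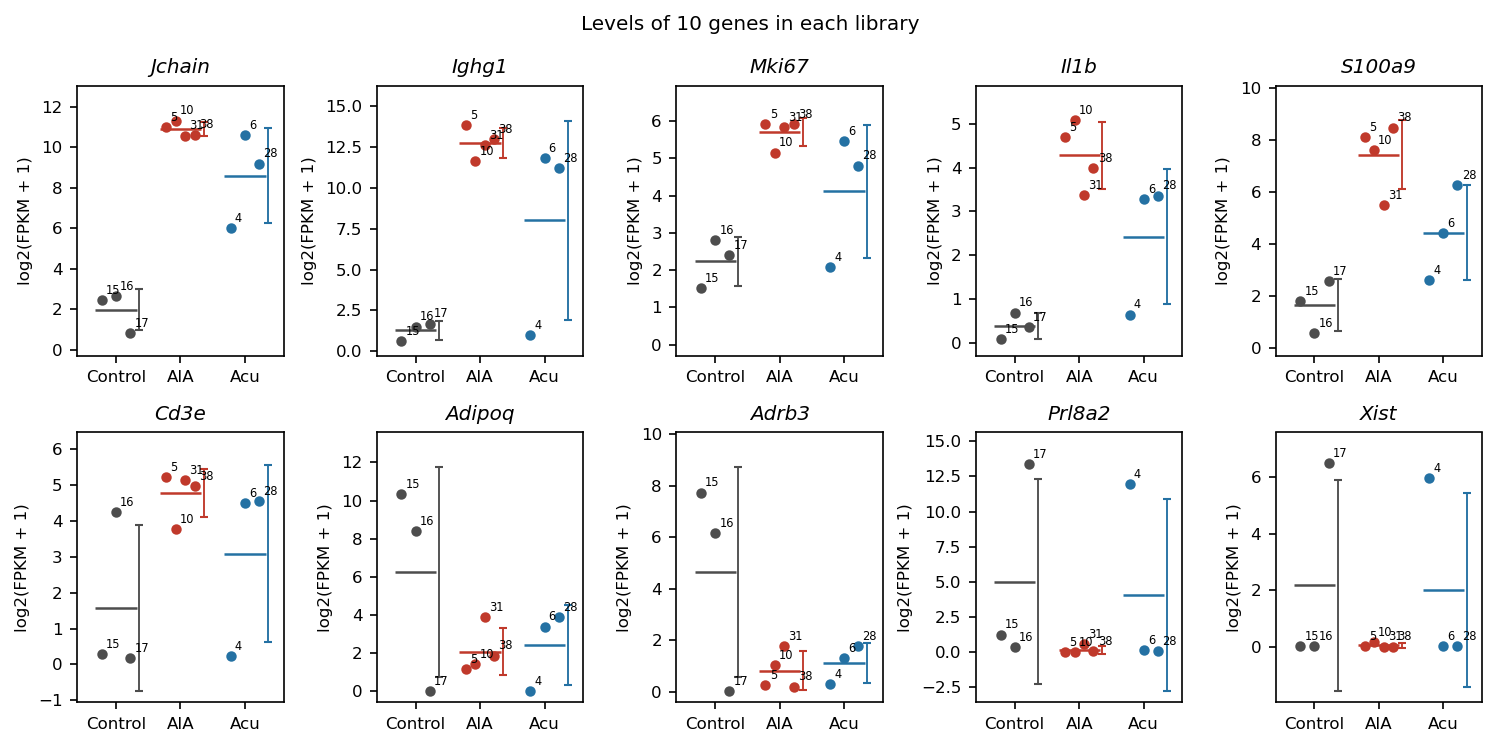
log2(FPKM + 1) (vertical axis) of 10 genes in each library, by group (horizontal axis). Points are libraries with their number, lines are group means and bars are SD. Prl8a2 reached 10782 FPKM in the library labelled Control 17, and Adipoq 1299 FPKM in Control 15.

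Acu was compared with AIA to ask what acupuncture changed in the arthritis model. Mki67 was 24.3 ± 19.9 FPKM in Acu (SD, n = 3) against 52.5 ± 12.1 FPKM in AIA (n = 4), a log2 difference of −1.60 (SE 0.71, limma adjusted p = 0.746). Il1b was 6.17 ± 4.87 against 20.5 ± 10.5 FPKM (−1.85, SE 0.67, adjusted p = 0.746). limma called 0 of 17010 genes, with 799 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0754. Groups did not overlap in 11.1% of genes against 5.71% by chance. voom called 0 and array weights called 98 (63 higher, 35 lower). Without the library labelled Control 17, 1 gene was called, Snord71 (adjusted p = 0.0270). Without the libraries labelled Control 17 and Acu 4, limma again called 0 of 16067, with 480 at an unadjusted p under 0.05. Genes above the filter only in Acu could not enter that fit.

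The gene with the smallest p was Mir6976, a microRNA gene of 63 bases, listed at 0 in all AIA and Control libraries and at 1.99 ± 0.405 FPKM in Acu (adjusted p = 0.0754). At most 3 reads per library stood behind it. Snord71, a small nucleolar RNA gene of 85 bases listed at 0 in all AIA libraries, had at most 8 reads. The mitochondrial tRNA gene mt-Ts2 stood at −2.76 (adjusted p = 0.521), Ovol3 at −1.69 and Il1f9, the inflammatory interleukin 36 gamma, at −1.48 (SE 0.32, adjusted p = 0.746). None passed.

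The B cell and T cell lists were called lower in Acu only where the library labelled Acu 4 was fitted. Over all 10 libraries the B cell list had a median of −1.68 and the T cell list −1.25 (camera adjusted p 1.41e-04 and 1.37e-04, and 0.454 for both with an estimated correlation). Without the library labelled Acu 4 the adjusted p was 0.868 for B cells, 0.609 for T cells and 0.283 for S phase genes. The naive T cell list went from −1.595 (camera adjusted p = 9.53e-05) to −0.20 without that library (camera adjusted p = 0.168). The germinal centre list had a median of −0.69 over all libraries (camera adjusted p = 0.00152, and 0.382 with an estimated correlation). That list averaged 2.69 in Acu 6 and 2.37 in Acu 28, against 2.38 to 3.06 in AIA. Without the libraries labelled Control 17 and Acu 4, Cd3e stood at −0.26, and camera's adjusted p was 0.800 for B cells and 0.555 for T cells. The G2/M median was −0.82 over all libraries (camera adjusted p = 3.64e-08, and 0.413 with an estimated correlation) and −0.24 without both (adjusted p = 0.00456, and 0.442 with an estimated correlation). Array weights over all libraries gave an adjusted p of 0.0879 for the G2/M list. Without both libraries Mki67 stood at −0.57 (SE 0.44) and Ube2c at −1.23, and S phase genes had a camera adjusted p of 0.229. Plasma cell genes had a median of −0.51 without both (adjusted p = 2.38e-04, but 0.361 with an estimated correlation and 0.268 with fry), with Eaf2 at −1.04 (SE 0.40) and Fkbp11 at −1.45. Among immunoglobulin genes Ighg3 stood at −2.08 (SE 0.89), Igkc at −2.09 (SE 1.53) and Ighg1 at −1.25 (SE 0.70). The unfolded protein response had a median of −0.47 (adjusted p = 3.20e-05, but 0.361 with an estimated correlation), with Manf at −1.07 (SE 0.38). Over all libraries its median was −0.25 (adjusted p = 0.0277, and 0.610 with an estimated correlation), which quantile scaling moved to 0.00795 (adjusted p = 0.534). Its adjusted p was 0.0829 without AIA 10, 0.0878 without AIA 38 and 0.538 without Acu 28, with the library labelled Acu 4 still fitted. In Acu 6 the plasma cell, G2/M and unfolded protein response lists averaged 6.25, 3.51 and 6.19. These lay inside the AIA ranges of 6.16 to 6.35, 3.15 to 3.72 and 6.08 to 6.45. Acu 28 lay below them, at 5.37, 2.84 and 5.51. Apart from the library labelled Acu 4, the lower means of these lists thus came from 1 library.

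Neutrophil, cytokine, interferon gamma and M1-type lists had negative medians in Acu against AIA both with and without these libraries. So did ribosomal protein and mitochondrial genes, but with an estimated correlation or fry no list was called. The macrophage and monocyte list went from −0.32 over all libraries to 0.00949 without both (camera adjusted p = 0.471). Complement stood at 0.13 over all libraries (camera adjusted p = 0.453). For neutrophils camera's adjusted p was 7.76e-06 over all libraries and 1.43e-06 without both, where the median was −0.58. With an estimated correlation these were 0.382 and 0.361. The list had 0 genes past the threshold over all genes tested and 2 of 19 lower adjusted over the list alone with all libraries. Stfa2l1, a neutrophil inhibitor of proteases, stood at −2.71 (SE 0.88), Ccl3 at −0.91 (SE 0.30), Il1b at −0.96 (SE 0.48) and Il1f9 at −1.37 (SE 0.35) without both. Cytokine, interferon gamma and M1-type genes had medians of −1.07, −0.89 and −0.76 over all libraries. Without both these were −0.35 (camera adjusted p = 1.35e-04), −0.32 (adjusted p = 0.00111) and −0.17 (adjusted p = 0.00752). With an estimated correlation the adjusted p without both was 0.361 for cytokines and 0.397 for the interferon gamma and M1-type lists. For M1-type genes array weights gave an adjusted p of 0.0879. AIA 38 had the highest mean of the AIA libraries for neutrophils (4.23 against 1.75 to 2.90), M1-type genes (4.08 against 3.34 to 3.66) and interferon gamma genes (5.86 against 5.22 to 5.29). For neutrophils AIA 31, at 1.75, lay below Acu 28, at 2.42. Without AIA 38 the medians of these lists over the other 9 libraries were −0.5956 (adjusted p = 0.01996), −0.6291 (adjusted p = 0.001183) and −0.795 (adjusted p = 2.245e-05). That fit still held the library labelled Acu 4, which averaged 1.51 for M1-type and 2.80 for interferon gamma genes. Acu 6 and Acu 28 averaged 3.16 and 3.54, and 5.02 and 5.22. For the M1-type and interferon gamma lists the fit therefore cannot show a lower level apart from that library. For neutrophils that library, at 1.80, lay between Acu 6, at 1.49, and Acu 28. Without both, 25 of 26 ribosomal protein genes stood lower, with a median of −0.59 (camera adjusted p = 1.55e-05, but 0.397 with an estimated correlation), and mitochondrial genes had a median of −0.49 (adjusted p = 0.00686, but 0.498). Over all libraries these medians were −0.73 (adjusted p = 3.18e-06) and −0.32 (adjusted p = 0.0402). Quantile scaling gave adjusted p-values of 0.364 and 0.444. Ribosomal protein genes averaged 10.02 in AIA 10 against 8.59 to 8.79 in the other AIA libraries. Their median was −0.3992 without AIA 10 (adjusted p = 8.933e-04), and −0.2331 without Control 15, AIA 10 and the libraries labelled Control 17 and Acu 4 (adjusted p = 0.008855). For mitochondrial genes the adjusted p was 0.0526 without Control 15, 0.324 without AIA 5, 0.168 without AIA 31, 0.0801 without AIA 38 and 0.437 without Acu 6. The M2-type list had an adjusted p of 0.758 over all libraries and 0.143 without both. The smallest adjusted p of any list with an estimated correlation was 0.382 over all libraries and 0.361 without both.

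Genes of polarization and of sympathetic signalling did not pass in Acu against AIA without the libraries labelled Control 17 and Acu 4. Tbx21 of Th1 cells stood at 0.50, Ifng at −0.25 and Foxp3 of regulatory T cells at 0.34. Nos2 stood at 0.64, Arg1 at −0.65, Mrc1 at −0.22, Tnf at −0.21 and Il10 at −0.16. Adrb3 stood at 0.71. The adrenergic list had a camera adjusted p of 0.768 over all libraries and 0.673 without both. Th, the enzyme that makes catecholamines, was listed at 0 in all AIA and Acu libraries. Muscle and adipocyte lists were not called over all libraries, with medians of 0.72 (camera adjusted p = 0.470) and 0.32 (adjusted p = 0.773). Muscle genes stood higher in Acu as a list without the libraries labelled Control 17 and Acu 4 (median 2.40, adjusted p = 8.30e-09), with Atp2a1 at 3.89 (SE 1.72), and adipocyte genes with a median of 1.14 (adjusted p = 9.25e-05), with Cidea at 1.67. With an estimated correlation the adjusted p-values without these libraries were 0.362 and 0.417, and fry gave 0.298 and 0.429. The AIA libraries ran from 1.04 to 6.10 for muscle and from 1.72 to 4.02 for adipocyte genes, with AIA 31 highest in both. Acu 6 and Acu 28 averaged 5.38 and 6.645 for muscle, and 3.59 and 3.99 for adipocyte genes. Only the muscle average of Acu 28 thus lay above the AIA range.

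Acu was compared with Control to ask how far treated nodes stood from nodes without adjuvant. Over all libraries limma called 0 of 17010 genes, with 1275 at an unadjusted p under 0.05 and a smallest adjusted p of 0.128. voom called 0 and array weights called 2067. Groups did not overlap in 9.15% of genes, against 10% by chance. Without the library labelled Control 17 limma called 299, and without the library labelled Acu 4 it called 85. Olfm2 stood at −2.32 (SE 0.30, adjusted p = 0.128), G0s2, an inhibitor of fat breakdown, at −3.51, Jchain at 6.62 (SE 1.00, adjusted p = 0.205) and Arg2 at 2.28. Adjusted over the list alone, 11 of 16 plasma cell genes, 5 of 22 cytokine genes, 4 of 16 complement genes and 2 of 24 G2/M genes were higher, as was 1 gene each of the M1-type and germinal centre lists. Lower were 5 of 7 erythroid genes and 1 of 16 adipocyte genes, and endothelium had 2 higher and 5 lower of 18. The other lists had 0, and over all genes every list had 0. Camera called 25 of 35 lists with the preset correlation and 0 with an estimated one.

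Without the libraries labelled Control 17 and Acu 4, limma called 713 genes between Acu (n = 2) and Control (n = 2), 143 higher and 570 lower. Without Control 15 as well it called 0, with 1942 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0528. In the first of these fits Ighg1 rose by 10.45 (SE 0.81, adjusted p = 0.0060), Slpi by 8.20 (SE 0.64, adjusted p = 0.0060) and Jchain by 7.33 (SE 0.61, adjusted p = 0.0060). Mzb1, Cd5l, Serpina3g, Clec4n, Plac8 and Fam46c rose by 3.76 to 5.89. Mki67 rose by 2.96 (SE 0.51, adjusted p = 0.0227), Ccnb2 by 2.37, Il1b by 2.91, Ccl2 by 3.56 and Clec7a by 3.53. Retnla fell by 5.30, Adrb3 by 5.41 and Maob by 2.69. Adipoq fell by 5.74 (SE 0.93, adjusted p = 0.0193), and Car3, Nnat, Thrsp, Cyp2e1, Sncg, Retn and Cfd by 5.76 to 6.04. The adipocyte average was higher in Control 15 and Control 16 than in Acu 6 and Acu 28. The falls of fat genes and Adrb3 thus cannot be assigned to the adjuvant or to acupuncture. Over all genes, with counts adjusted over the list alone in brackets, 11 (22) of 24 G2/M genes, 8 (15) of 16 plasma cell genes, 3 (9) of 22 cytokine genes and 0 (15) of 22 interferon gamma genes were higher. The M2-type list had 2 (3) higher and 5 (7) lower of 16, and 15 (16) of 16 adipocyte genes were lower. Igkc (6.03, adjusted p = 0.0936) and Il10 (1.57, adjusted p = 0.0921) did not pass.

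The share of summed FPKM taken by 429 immunoglobulin genes was 0.388 ± 0.627% in Control (SD, n = 3), 30.5 ± 10.04% in AIA (n = 4) and 11.5 ± 10.4% in Acu (n = 3). AIA exceeded Control by 30.1 percentage points (two-sided exact permutation p = 0.0571, adjusted over 3 comparisons 0.129, smallest possible 0.0286). Acu differed from AIA by −18.9 points (two-sided exact permutation p = 0.0857, adjusted 0.129). Acu differed from Control by 11.1 points (two-sided exact permutation p = 0.200, smallest possible 0.1). The library labelled Acu 4 had 0.369%, Acu 6 20.8% and Acu 28 13.4%. Without the library labelled Acu 4 the Acu and Control difference was 16.7 points, and without Acu 6 it was 6.49 points. Without the libraries labelled Control 17 and Acu 4 the 3 differences were 29.9, −13.4 and 16.5 points.

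**Figure D3:**
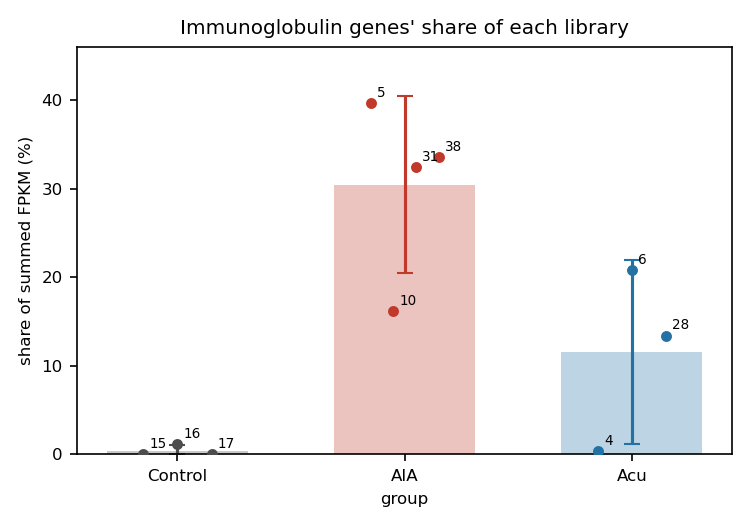
Share of summed FPKM from immunoglobulin genes in percent (vertical axis) by group (horizontal axis). Bars are means, error bars are SD with the lower bar of Control stopped at 0, and points are libraries, from 16.2% to 39.7% in AIA.

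The comparisons were joined to ask whether acupuncture moved genes back toward Control. No gene was called in both AIA against Control and Acu against AIA in limma, so 0 were called in opposite directions, where independent lists would share 0. With array weights 26 genes were. Across 17010 genes, which are not independent replicates, the fold changes of AIA minus Control and Acu minus AIA had a correlation of −0.746. Simulated unchanged groups that share the AIA libraries gave −0.453 to −0.398. They drew each gene independently, so the simulated ranges here are narrower than genes that vary together would give. They also gave all groups the same spread for a gene. The B cell list, however, had an SD of 0.334 in AIA against 3.12 in Control and 3.35 in Acu. For such genes the simulation may overstate what sharing the AIA libraries gives. The covariance was −0.603 against a simulated mean of −0.145, a difference of −0.458. Without the libraries labelled Control 17 and Acu 4 the correlation was −0.315, within the simulated range of −0.363 to −0.297, and the covariance was −0.203 against −0.0802. Without Control 15 as well the correlation was −0.353, below the simulated range of −0.289 to −0.209, and the covariance was −0.198 against −0.0735. With the AIA libraries split 2 and 2, so that no library was shared, the 6 correlations ran from −0.360 to 0.0385 without the first pair and from −0.389 to 0.0450 without Control 15 as well.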

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

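The tests of the libraries labelled Control 17 and Acu 4, and of fat and of the sex of the animal in Control 15, were chosen only after the result was seen.

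Interferon gamma response genes averaged 5.855 on the log2(FPKM + 1) scale in AIA 38, against 5.223 to 5.293 in the other AIA libraries. Serpina3g, an interferon-driven protease inhibitor, stood at 8.623 in the same library, against 6.96 to 7.205. Igkc stood at 17.21 in AIA 5, against 16.48 to 16.56. In AIA 10 ribosomal protein genes took 22.44% of summed FPKM, against 6.764% to 7.849% in the other AIA libraries, and their list averaged 10.02 against 8.594 to 8.794. In the same library Mki67 stood at 5.151 (5.834 to 5.924 elsewhere in AIA), Foxp3 at 1.552 (2.975 to 3.099), Nos2 at 0.4236 (2.317 to 2.668) and Ighg2c at 6.851 (11.61 to 12.36). The microRNA genes Mir7030 and Mir6904 stood at 1.528 and 0.8824 in AIA 31 and at 0 in the other AIA libraries, from 2 reads and 1 read. Each value lay far from the other 3 libraries of its group by a gap test on 104 values, which found 11. Chance gives about 1 in 20 groups such a gap. AIA 10 held 6 of the 11, and no cause was tested for it.

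Prolactin-family and other decidual genes, with trophoblast genes, filled the libraries labelled Control 17 and Acu 4, and 0 of the 13 decidual genes is in another list. A response to the treatment is argued against, because the median decidual gene of the same group's other libraries was at most 0.03711% of its level there (0.02548% in the other group). A small admixture of uterus in a node is also argued against. The median B and T cell gene was 0.526% of its level in the other Acu libraries for the library labelled Acu 4, and 0.367% for the library labelled Control 17. What stays open is another tissue, of a female animal, under these labels, which may be a mislabelled or exchanged sample: the median Y-linked gene was at most 0.1582% of its level elsewhere and Xist at least 60.33 FPKM.

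Adipoq, Cfd and other fat genes were highest in Control 15, which held few lymphocyte genes. Tissue of a female animal is argued against, because the median Y-linked gene was 96.11% of its AIA level. A node that lost lymphocytes and kept its stroma is also argued against, because the median of 5 stroma genes was 1.906% of its level in Control 16, from 0% to 37.7%. All 5 genes are also in another list. Fat as nearly all of the library was tried as an explanation: the median B and T cell gene was 0.9146% and the median adipocyte gene 407.8% of its level in Control 16. These values restate the pattern, so they are no independent test of it. Muscle genes averaged 6.92 and nerve and Schwann cell genes 4.23 in Control 15, so other tissue was present too. A large share of fat stays open and may explain the pattern. No explanation by the treatment of its group was tested for Control 15.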

How the results depend on the processing

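The fits without Control 15, Control 17, Acu 4 or AIA 10 together, and voom, were chosen only after the result was seen.

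For AIA against Control the 4 genes became 0 with a pseudocount of 0.1, voom or an adjusted p under 0.01. They became 1 without a filter, 60 (24 higher, 36 lower) at an FPKM of at least 1, 33 (15 and 18) with quantile scaling, 638 (277 and 361) with only the 2 groups fitted and 3319 (1398 and 1921) with array weights. Scaling without immunoglobulin and T cell receptor genes gave 6 (4 higher and 2 lower, 3 of them shared) and moved the median of all genes from −0.07, 0.08 and 0.02 to 0.06, 0.27 and 0.35 in the 3 comparisons. The count was 2166 without the libraries labelled Control 17 and Acu 4, 486 without Control 15 as well and 1832 without AIA 10 as well. Leaving out 1 library gave 0 to 1708.

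Acu against AIA went from 0 to 2 without a filter (Mir6976 among them), 98 with array weights and 0 to 1 leaving out 1 library. Acu against Control went from 0 to 1 without a filter (Mir6976) and 2067 with array weights. It went to 713 without the libraries labelled Control 17 and Acu 4, to 1005 without Control 15 and AIA 10 as well, and to 0 to 299 leaving out 1 library. Genes called in opposite directions numbered 26 with array weights and 0 to 1 leaving out 1 library. The correlation of −0.7461 was −0.3401 with array weights, −0.3153, −0.3534 and −0.4035 without the 2, 3 and 4 libraries, and −0.8041 to −0.3099 leaving out 1.

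Of the genes named, 3 passed over all libraries. This became 0 with a pseudocount of 0.1 or voom, 18 at an FPKM of at least 1, 14 with quantile scaling, 45 with only the 2 groups fitted and 146 with array weights. Without the 2, 3 and 4 libraries it was 91, 27 and 93, and leaving out 1 gave 0 to 87. Of the 105 list comparisons camera called 70, 0 with an estimated correlation and 60 to 71 leaving out 1 library.

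Some directions reversed. In Acu against AIA the macrophage list went from −0.32 to 0.1262 with array weights. The dendritic cell list went from −0.46 to 0.05931 and 0.06002 without the 2 and 3 libraries, and to −0.695 to 0.05708 leaving out 1. The B cell list went from −1.68 to 0.07423 without the library labelled Acu 4 and to 0.07658 and 0.07729 without the 2 and 3 libraries, with camera pointing up in the last of these alone. In Acu against Control the fibroblastic list (−0.22, with camera pointing up) ran from −1.13 to 0.183 leaving out 1 library. In AIA against Control Prf1 went from −0.67 to 1.857 without the 2 libraries, and Tnfrsf9 from −0.08 to 2.224 and, without 4, 1.432.

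The cause was not tested for any of these changes, except that fewer libraries were fitted where libraries were left out. Deposited FPKM without further scaling, a pseudocount of 0.5, robust empirical Bayes and a fold threshold of 2 kept the counts of 4, 0 and 0. Over all settings, lists stayed on their side of camera's threshold in 2299 cases, where 2235 medians kept their direction and 64 turned. They became past it in 75 (all kept), lost it in 140 (11 turned) and reversed in camera's direction in 6. Named genes stayed on their side in 8846 cases (8702 kept their direction and 144 turned) and, with a move beyond the spread between replicates, in 378 (5 turned). They became past it in 865 and lost it in 29 (all kept), and reversed in 3. No paired analysis was possible because the groups share no replicate numbers. At the depth of 13269763 to 18926894 reads, genes of few reads such as the microRNA genes could not be measured well.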

Other observations

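The splits of the libraries and the test of the shared AIA libraries were set before the results were seen, and the fits without Control 15, Control 17 and Acu 4 in this part were chosen after.

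The adjuvant comparison called 4 genes, and 2 of the 35 splits of the same 7 libraries called as many, so chance cannot be excluded. The highest other split called 26 genes and set AIA 5, 31 and 38 against the Control libraries with AIA 10. For Acu against AIA the real count was 0, with a highest other count of 4. Any split calls at least 0, so the 35 of 35 splits that called as many say nothing about chance. For Acu against Control the 10 splits are too few for a share under 0.05, with a real count of 0 and a highest other count of 2359. That split set Control 15 with the libraries labelled Control 17 and Acu 4 against Control 16, Acu 6 and Acu 28. It calls many genes, which points to a structure of the samples: those first 3 libraries are the ones low in B and T cell genes.

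Genes such as Mki67, Il1b and Ighg1 stood higher in AIA than in Control and lower in Acu than in AIA, and across genes the fold changes had a correlation of −0.7461. The correlation lay below the −0.4529 to −0.3982 that simulated unchanged groups sharing the AIA libraries reached. Those groups drew each gene independently, so their range is narrower than genes that vary together would give. They also gave all groups the same spread for a gene, which the real groups did not have. Lying outside that range therefore cannot by itself exclude the shared AIA libraries alone. Other tissue in the libraries labelled Control 17 and Acu 4 is a candidate cause. Both held decidual genes, but trophoblast genes averaged 2.59 in the first and 8.80 in the second. With the AIA libraries split 2 and 2, so that no library was shared, the correlation averaged −0.539 over all 10 libraries, from −0.701 to −0.376. Every split was thus below 0 with no library shared, which argues against the shared AIA libraries alone over all 10 libraries. With the libraries labelled Control 17 and Acu 4 left out the correlation averaged −0.1518, from −0.36 to 0.0385. Without Control 15 as well it averaged −0.1559, from −0.3894 to 0.04502. Fewer libraries were then fitted, and both of these later ranges span 0. By these splits the other tissue and a move of adjuvant-changed genes back under acupuncture cannot be told apart. Without the library labelled Acu 4 alone, and with the AIA libraries shared, the correlation was −0.3099. The size of −0.7461 therefore depended on that library. A move back among the remaining libraries is neither shown nor excluded. The values near 0 or above (−0.0430, 0.0259 and 0.0385 without the first pair) came from splits with AIA 10 on the Acu side.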
